A study of Mus musculus with 89 samples.

How the data were processed

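The assay read sgRNA sequences from genomic DNA of transferred NK cells. Each sgRNA sequence marks the gene that its cell was aimed to lose, so its read number stands for the abundance of such cells. Per the labels, DNA came from dissected tumors, spleens and cell pellets taken before injection, and nested PCR amplified the sgRNA cassette ahead of sequencing. The deposited table held raw read counts per sgRNA, made by the authors, with no normalization per the file headers and the values. The submitters' processing notes name cutadapt 3.2, Bowtie 1.3.0 and MAGeCK, and their settings were not given in the sources used here. PCR reads carry no molecular identifiers, so intervals and floors cover counting error only.

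Groups came from the sample labels: 9, 10, 7 and 11 mice with B16F10, E0771, Pan02 and GL261 tumors, 7 cultures, 2 spleens of mice given saline in each of Pan02 and GL261, and 2 spleens without a tumor library in each of B16F10 and E0771. The table had 89 count columns. Of these, 15 matched 1 sample each, while 74 carried the name of a mouse that headed 2 columns, 1 for its tumor and 1 for its spleen. Which column was which could not be read from the names, and column order or values were not used to decide it. The comparisons planned before the data were examined, tumor against spleen and either tissue against culture, were therefore not run. In their place the 2 columns of each of the 37 mice were added and mice were compared with cultures, per model and over all 4 models with equal weight, and between models, or a measure was used that stays the same when the columns are exchanged. All comparisons of this kind were chosen after the layout of the table had been seen. Count columns that matched no sample numbered 0.

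Counts of the sgRNAs of a gene were summed, with the non-targeting sgRNAs as 1 further feature. The test was edgeR's quasi-likelihood F test (glmQLFit with robust settings, version 4.0.16, R 4.3.3) with edgeR's filterByExpr filter and Benjamini-Hochberg adjustment, called at 0.05. The plan had been TMMwsp scaling. It was fitted first and its calls were seen. Its factors ran from 0.0132 to 3.81, while under total counts the non-targeting log2 change lay between -0.15 and 0.28, and total counts were then made the main scaling. Genes called under total counts and under TMMwsp numbered 0 and 0 in B16F10, 57 and 9 in E0771, 3 and 0 in Pan02, 5 and 2 in GL261, 5 and 1 over all mice, and 37 and 1239 between models. Gene lists were tested with limma's camera (version 3.58.1) at a preset correlation of 0.01 and with an estimated one.

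Retention counted an sgRNA as kept in a mouse with 10 reads or more. Thresholds of 1, 10 and 100 reads, with and without B16F10 mouse 1, had been looked at before 10 was taken, and each gave 0 genes over all mice. Expected numbers came from the number of mice retaining each sgRNA, in 50 bins of sgRNAs of like culture abundance. For a gene, p came from the exact distribution of the sum over its sgRNAs, taken as independent draws. Only the count of mice with a non-targeting ratio below 1 used the bins within each mouse. Matching on GC content used coarser abundance bins crossed with bins of GC content. A filter for reads that may have passed between libraries set a count to 0 when it was under 2% of that sgRNA's highest count in a library of another animal. It was chosen after such ratios had been seen, and removed a median of 38.3% of the retained sgRNAs of a mouse (7.14 to 91.9) but 1.54% of its reads. Dominant sgRNAs held 2% or more of a library's reads and were set against 10000 permutations of the gene labels. Complexity was compared by exact permutation of the mean difference, or by 100000 resamples with 10 or more mice on both sides, in a family of 40 tests. Shares of counts have Wilson intervals.

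Genes were named by a rule fixed beforehand and carried over from tumor and spleen to the mouse comparisons: Calhm2 everywhere, the 10 called genes of lowest p in each direction over all mice, the 3 in each direction per model, the 3 of lowest p in each direction where none was called, every list member called over all mice with 2 further members of each list by size of change, and the 5 genes with most dominant events. For retention, the 3 of lowest p in each direction were named by analogy, and olfactory receptors and the follow-up of Chrnb1 in B16F10 mice were added after their values were seen. So were the tables of each gene's share in single mice, of the top sgRNAs of the cultures and of gene families among the E0771 calls. Names were used as in the table; 2825 of 2863 matched symbols and 18 matched synonyms in the RefSeq table of GCF_000001635.26, used for names only, and 20 had no match. Of the sgRNAs, 517 of 70 genes shared a spacer with another gene's sgRNA and all of these had 0 counts in the cultures. In total 1362 sgRNAs had 0 counts in every culture, and 4 genes had no counted sgRNA.

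The edgeR fits were tested on data simulated from the real means and library sizes. A first version with 4-fold and 16-fold changes recovered almost no rises, and 64-fold changes were then added, with 40 genes per size and direction among 2860 features. Rises of 64-fold were recovered for 57.5% of genes in B16F10, 45% in E0771, 67.5% in Pan02, 52.5% in GL261 and 0% over all mice, and rises of 4-fold for 0% in each. Losses of 16-fold were recovered for 92.5%, 95%, 77.5%, 90% and 100% in the same order. Between models, with 2858 features, 65% of the 64-fold rises and 10% of the 16-fold losses were recovered. False calls were 35 of 137, 30 of 126, 48 of 147, 18 of 115, 2 of 82 and 6 of 57 calls in the order B16F10, E0771, Pan02, GL261, all mice and between models. The raised genes also raised the totals used for scaling, so unchanged genes shifted lower in the changed group. After scaling, losses were thus larger and rises smaller than named. The false calls may come from that shift and need not give the error rate of the real fits. With nothing changed, 2 genes were called in Pan02 and 0 in the others. Rises of 16-fold were recovered for 12.5% or fewer of the genes in each comparison. For the retention test, the real retained counts were shuffled among sgRNAs of the same abundance bin, and 50 genes per size were then changed. The test over 2859 genes recovered 28%, 78%, 66% and 100% of genes changed 1.5, 2, 0.5 and 0.25 times, with 2 false calls. Shuffling makes the sgRNAs independent, as the test assumes, so these values cannot check that assumption.

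Depth per mouse library had a median of 3607699 counts, and 4 libraries lay under 100000. Alternatives were TMMwsp, TMM, size factors from non-targeting sgRNAs, DESeq2 (1.42.0), limma-voom with quality weights, no filter, sgRNAs capped at the 99th percentile, the number of sgRNAs detected, counts under 10 set to 0, removal of shared spacers, equal weight for both libraries of a mouse, the filter for passed reads, removal of shallow mice, sgRNA-level scores, and leaving out each mouse or culture. The number of sgRNAs detected was taken as log2 with 1 added and scaled to the total detected in the mouse or culture. A gene with few readable sgRNAs that is absent from the mice can thus get a positive value. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.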

Results

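Natural killer (NK) cells are lymphocytes that kill tumor and virus-infected cells. The screen put a virus-delivered library of single guide RNAs (sgRNAs), which direct the Cas9 nuclease to cut chosen genes, into cultured NK cells of Cas9 mice and transferred these cells into mice bearing tumors. The library held 61911 sgRNAs, of which 5000 were non-targeting controls and the rest were aimed at 2863 genes of the cell surface, 2813 of them with 20 sgRNAs each. Mice carried B16F10 melanoma (9 mice), E0771 breast carcinoma (10 mice), Pan02 pancreatic carcinoma (7 mice) or GL261 glioma (11 mice), and 7 libraries came from the cultured cells before injection. B16F10 and E0771 mice received 4000000 NK cells and were taken at day 20. Pan02 and GL261 mice received 2000000 NK cells and were taken at day 24 and day 27. Each of these 37 mice gave a tumor library and a spleen library, and the sgRNA counts of both were added, since the columns of the count table named the mouse but not which of its 2 tissues they held. The values therefore describe the cells sampled in tumor and spleen together, weighted by reads, and tumor was not set against spleen. In E0771 mice 4, 5 and 7 and in GL261 mouse 8, nearly all reads came from 1 of the 2 libraries. Total counts ran from 52211 to 5647118 per mouse library (median 3607699) and from 3785469 to 5759283 in the cultures. Labels name separate animals but not separate cultures, so the spread between the culture libraries may be technical.

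On average, most sgRNAs read in culture were not read in a mouse, and a few of those read took a large share of the reads. Whether the unread sgRNAs were lost from the NK cells or missed in the cells and DNA sampled was not tested. The cultures held 60536 ± 4 of the sgRNAs (SD, n = 7), against 20671 ± 14099 in B16F10 mice (n = 9), 19599 ± 10285 in E0771 mice (n = 10), 13284 ± 6041 in Pan02 mice (n = 7) and 12527 ± 5254 in GL261 mice (n = 11). Each model fell below the cultures, with adjusted p = 0.00105 for B16F10, 0.000294 for E0771, 0.00155 for Pan02 and 0.000294 for GL261 (two-sided exact permutation test of the means, Benjamini-Hochberg over 40 tests). Counted as sgRNAs with 10 reads or more, the median was 60017 in culture, 4818 in B16F10 mice, 3480 in E0771 mice, 3227 in Pan02 mice and 3045 in GL261 mice. With counts under 2% of the same sgRNA's highest count in another animal set to 0, these medians were 2186 in B16F10, 1273 in E0771, 2760 in Pan02 and 2095 in GL261 mice, in another order. The most abundant sgRNA took 0.0218% ± 0.0151 of the reads in culture (n = 7), 1.88% ± 1.23 in B16F10 mice (n = 9), 0.561% ± 0.305 in E0771 mice (n = 10), 8.27% ± 6.91 in Pan02 mice (n = 7) and 6.44% ± 7.41 in GL261 mice (n = 11). This share rose over culture in B16F10 (adjusted p = 0.00432), E0771 (0.00155) and Pan02 (0.00155) by the exact permutation test, and the GL261 difference of 6.42 points missed the threshold (adjusted p = 0.0515). That test compared means, and the GL261 mice varied widely. Every GL261 mouse still lay above every culture, with a lowest share of 0.460% against a highest of 0.0551% in culture.

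The tumor models differed in the share of reads held by the most abundant sgRNA. B16F10 mice had a higher top share than E0771 mice (by 1.31 points, adjusted p = 0.00702, exact permutation test). E0771 mice had a lower one than Pan02 mice (-7.71 points, adjusted p = 0.000294, exact permutation test) and GL261 mice (-5.88 points, adjusted p = 0.00658, permutation test), as did B16F10 mice against Pan02 mice (-6.39 points, adjusted p = 0.00197, exact permutation test). B16F10 and GL261 mice differed by -4.57 points (adjusted p = 0.148) and Pan02 and GL261 mice by 1.83 points (adjusted p = 0.703), both within the spread by the exact permutation test. The numbers of sgRNAs detected did not differ between any pair of models, with the lowest adjusted p at 0.109 between E0771 and GL261 mice. B16F10 mouse 1 kept 45325 sgRNAs at 10 reads or more, next to 5820 in the B16F10 mouse closest to it. A B16F10 excess over GL261 of 5634 sgRNAs on this measure (adjusted p = 0.0490, exact permutation test) rested on that mouse and was 1086 without it (adjusted p = 0.239, exact permutation test). B16F10 and E0771 mice shared their doses of NK and tumor cells and their day, while Pan02 and GL261 mice differed from these in both doses and day, and from each other in tumor cell dose and day.

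**Figure D1:**
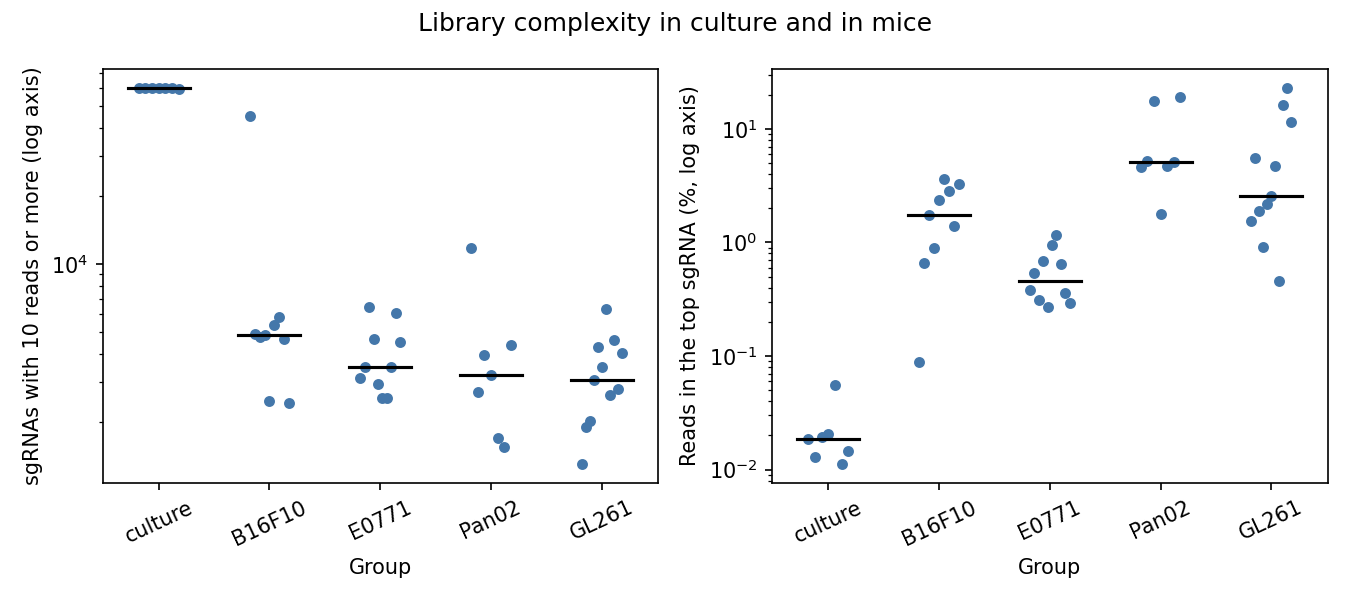
Left, number of sgRNAs with 10 reads or more (log axis) in each culture library and each mouse; right, percent of reads held by the most abundant sgRNA (log axis), with groups on both x axes. Points are libraries or mice, bars are medians, and the medians on the left fall from 60017 in culture to between 3045 and 4818 in the mice (1273 to 2760 with the 2% filter, not drawn).

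Dominant sgRNAs were those that held 2% or more of the reads of 1 library. There were 354 such events in 24 mice, and in each of these mice they lay in 1 of its 2 libraries. B16F10 mice gave 109 events (6 of 9 mice), E0771 mice 4 (1 of 10), Pan02 mice 107 (7 of 7) and GL261 mice 134 (10 of 11). Without the 4 shallow mice, those with a library under 100000 reads, there were 347 events in 22 mice, with E0771 at 0 and GL261 at 131: all 4 E0771 events lay in the library of E0771 mouse 5 with 52751 reads, where most sgRNAs had far more reads in another animal. The events fell on 289 genes, and no gene passed (permutation of gene labels, Benjamini-Hochberg; the highest count was 3 events and permuted labels gave a median highest count of 3, p = 0.969). Enpp1, an ectoenzyme that hydrolyses extracellular nucleotides, had those 3 events, all from 1 of its sgRNAs in mice of 2 models (p = 0.0005, adjusted p = 0.0942), 1 of them in the GL261 mouse 8 library of 52211 reads. H2-T10, a nonclassical class I gene, Dlk2, a Notch pathway ligand homologue, Slc34a2, a sodium and phosphate cotransporter, and Clec1a, a C-type lectin, had 2 events each, with the same adjusted p of 0.0942, and 1 event of Slc34a2 lay in that GL261 mouse 8 library too. Adjustment covered only the 289 genes with an event. By the same permutation test, genes with 1 event had an adjusted p of 0.116 to 0.118, so 0.0942 is no near miss. Without the shallow mice the highest count was 2 events (Enpp1 among these genes, p = 1.00 for the highest count), and 347 events fell on 346 sgRNAs, against 354 on 347 with them. Non-targeting sgRNAs made up 37 of the events, 10.5% (95% Wilson interval 7.68 to 14.1, counting error only), next to 8.26% of the sgRNAs counted in culture (p = 0.171).

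Which genes helped or hindered persistence was first asked by counting sgRNAs, so that 1 dominant sgRNA weighs no more than any other. An sgRNA with 10 reads or more in a mouse counted as retained there, and each gene was set against sgRNAs of like abundance in culture. Chrnb1, the muscle nicotinic receptor beta subunit, was retained 113 times where 65.7 were expected, and Olfr271-ps1, an olfactory receptor pseudogene, 89 times for 53.6, and the protocadherin Pcdhgb7 88 times for 52.1. At the other end, Casd1, a sialic acid O-acetyltransferase, was retained 35 times for 65.0, Megf11 28 times for 54.5 and Lrrc15 33 times for 61.5. None of the 2859 genes passed after adjustment, these included (exact test of the retained count, Benjamini-Hochberg, with the lowest adjusted p 0.270 for Chrnb1). An unadjusted p under 0.05 was found for 131 genes, no more than chance alone would give. Calhm2, the ion channel subunit named in the series title, was retained 60 times where 67.9 were expected (p = 0.503). Its ratio was 0.882 in B16F10, 0.916 in E0771, 0.931 in Pan02 and 0.813 in GL261 mice, with none of these 4 past the threshold. Within single models Chrnb1 passed in B16F10 mice, with 55 retained for 27.8 (adjusted p = 0.00902, exact test). No gene passed in E0771, Pan02 or GL261 mice. There 95, 95 and 94 genes had an unadjusted p under 0.05, again no more than chance would give. Chrnb1 stood above the threshold without B16F10 mouse 1 too (37 for 12.8, adjusted p = 0.0289), but not once counts under 2% of the same sgRNA's highest count in another animal were set to 0 (24 for 17.2, adjusted p = 1.00), nor with 1 or 100 reads as the minimum. In retained counts shuffled within abundance bins, with known changes added, this test over all mice recovered 78% of genes retained 2 times as often. It recovered 66% of those retained 0.5 times as often.

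By the same measure the 13 groups of genes fixed before the data were examined had ratios of observed to expected retention between 0.884 and 1.06. Sets with ratios above 1 were the inhibitory receptors of NK cells (1.06, 18 genes), taste receptors (1.04, 28 genes), cytokine receptors (1.03, 22 genes), activating and costimulatory receptors (1.03, 22 genes) and antigen presentation genes (1.02, 8 genes). Ratios just under 1 were found for adhesion and tissue egress genes (0.997, 24 genes), adenosine and prostaglandin receptors with their ectoenzymes (0.996, 14 genes), TGF-beta superfamily receptors (0.981, 11 genes), death receptors (0.980, 6 genes) and chemokine receptors (0.976, 20 genes). Transporters needed for growth (0.934, 13 genes), B and T cell lineage genes (0.932, 14 genes) and the calcium homeostasis modulator family, of which Calhm2 alone was in the library (0.884), had the lowest ratios. None of the 13 passed (permutation of sgRNAs within culture abundance bins, Benjamini-Hochberg; lowest adjusted p 0.548). Non-targeting sgRNAs were retained less often than targeting ones, 14928 times for 15511 expected. The ratio was 0.962 (95% bootstrap interval over the non-targeting sgRNAs, with the mice held fixed, 0.942 to 0.982) and fell below 1 in 32 of 37 mice. Matched on the GC content of the spacer as well, with coarser bins of culture abundance, the ratio was 0.972 (0.951 to 0.993).

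**Figure D2:**
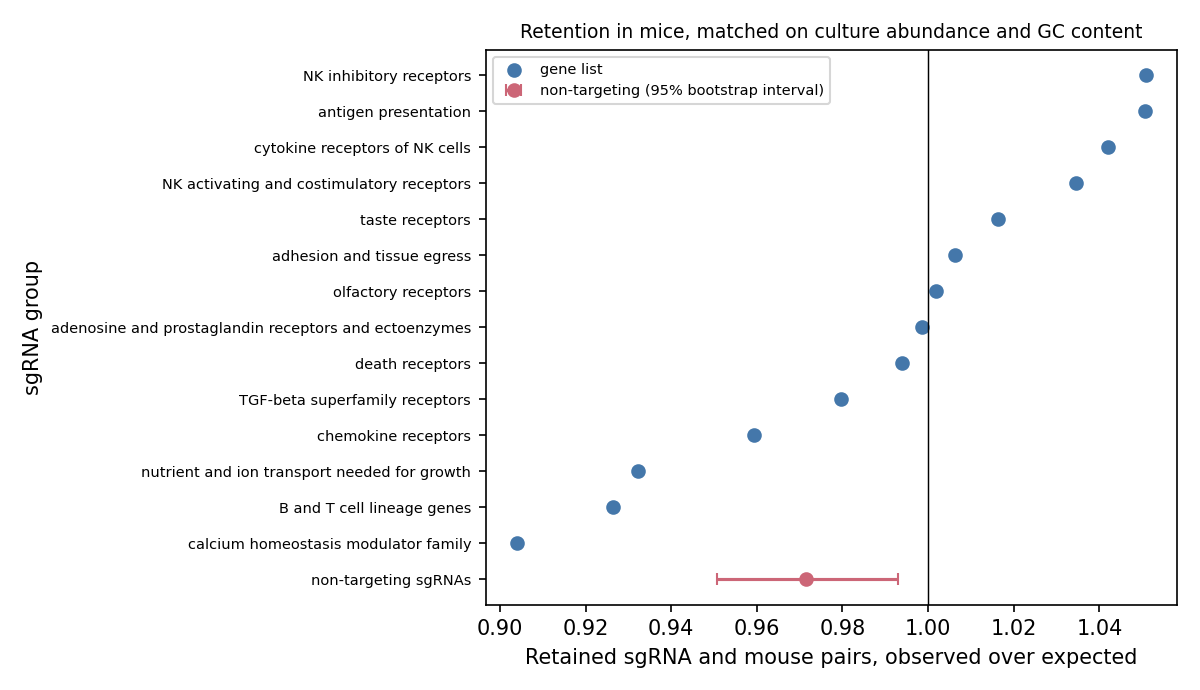
Retained pairs of sgRNA and mouse, observed over expected (x axis), for the fixed gene lists, the olfactory receptors and the non-targeting sgRNAs (y axis), with expected values matched on culture abundance and GC content. Each point is a ratio, the bar is a 95% bootstrap interval over the non-targeting sgRNAs, and the non-targeting ratio is 0.972 while the lists lie between 0.904 and 1.05.

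Summed reads per gene then compared all mice with culture. Of 12 genes with at most 4 readable sgRNAs, 5 were called lower in mice. No gene was called higher, by a test that recovered 0% of simulated 64-fold rises in this comparison, which were smaller once scaled. Gm44579, a predicted gene, had a log2 fold change of -8.79 ± 1.33 (SE, 37 mice against 7 cultures, adjusted p = 1.13e-07, edgeR quasi-likelihood test), was lower than the culture mean in 37 of 37 mice and had no read in 31 of them. Evi2 followed at -6.18 ± 1.09 (adjusted p = 2.10e-05, lower in 36 mice), Gm49368 at -5.22 ± 1.21 (0.0149, 36 mice), Gm13769 at -5.18 ± 1.26 (0.0295, 35 mice) and Cd300ld3, a member of the CD300 receptor family, at -4.85 ± 1.22 (0.0381, 36 mice). These 5 of the 2859 genes passed, all lower, and each rested on 1 to 4 sgRNAs that were read at all, with culture levels of 4.56 to 54.6 CPM (counts of a gene scaled to the total of the library). By the count of retained sgRNAs their observed over expected ratios were 0, 0.872, 0.762, 0.551 and 0.731 in the order given. None passed by that measure. Evi2, Gm44579 and Gm49368 share 19, 16 and 18 of their 20 spacers with Evi2a and Evi2b, with Olfr288 and with Itgam, and all such shared sgRNAs had 0 counts. The median gene moved by -0.68 on the log2 scale and the non-targeting sum by 0.02. Calhm2 stood at -1.01 ± 1.11 (p = 0.362, adjusted p = 0.982), below the culture mean in 30 of 37 mice, with a highest mouse value of 3432 CPM in E0771 mouse 2. Which way most genes moved depended on the tool: DESeq2 called 1837 genes higher and 0 lower, limma-voom 0 higher and 2858 lower, and counting detected sgRNAs 94 higher and 2 lower, with Evi2 (1.20), Gm49368 (0.78), Gm13769 (0.46) and Cd300ld3 (1.38) turned to the other sign. In the same order, those genes had no read in 33, 28, 18 and 26 of the 37 mice. Their turned sign can come from the added 1 and the scaling alone. Calhm2 turned too, to 0.50 with TMMwsp scaling, 0.55 by DESeq2 and 0.10 counted as sgRNAs detected, and stood at -4.11 under voom. The median gene stood at 1.69, 2.81, 0.16 and -3.42 in these settings, and Calhm2 lay below it in each. Its sign there therefore follows the scaling of all genes. By sgRNA-level scores (mean z) Calhm2 lay above the median gene, at 0.47 against 0.073. At least 1 alternative setting put Calhm2 past the threshold, where voom called 2858 of 2859 genes and DESeq2 1837, so passing there does not single it out. With TMMwsp scaling, which had been planned, 1 gene was called instead of 5, with TMM or capped sgRNAs 2, by sgRNA-level scores 0, and 3 without Pan02 mouse 3, 4 or 6, any 1 culture or the shallow mice.

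The direction of the gene lists depended on the scaling. With total counts 2493 of 2859 genes and 177 of the 201 list members were lower in mice, and 107 of the 201 lay below the median gene. With TMMwsp scaling 196 members were higher and 5 lower (median gene 1.69), by DESeq2 191 and 10 (2.81), with TMM 124 and 77 (0.15), counted as sgRNAs detected 154 and 47 (0.16) and by voom 0 and 201 (-3.42). Size factors from non-targeting sgRNAs kept the direction of total counts, with 31 members higher and 170 lower (-0.55), as did capped sgRNAs, with 56 and 145 (-0.26). The counts of lower and higher members given for each list are those of total counts. None of the 13 lists passed a test of a shift in summed reads, and in this comparison of all mice no member of any list was called over all genes tested. Among inhibitory receptors, 17 of 18 members were lower and 1 higher in mice, with Klrb1b, a lectin-like receptor, at -3.31 ± 1.27 (5 sgRNAs read) and Sigirr, a negative regulator of interleukin-1 family signals, at -1.61 ± 1.10. Activating and costimulatory receptors had 20 of 22 members lower and 2 higher, among them Cd28 at -2.17 ± 1.28 and Cd244a at -1.88 ± 1.15. Of 22 cytokine receptors 18 were lower and 4 higher, with the interferon-gamma receptor chain Ifngr2 at -1.98 ± 1.08 and the interleukin-4 receptor chain Il4ra at -1.47 ± 1.20. TGF-beta superfamily receptors were lower in 10 of 11 cases and higher in 1, for example Eng at -1.66 ± 1.17 and Acvrl1 at -1.24 ± 1.16. Chemokine receptors counted 17 lower and 3 higher of 20, including Ackr3 at -1.29 ± 1.15 and Cxcr3 at -1.29 ± 1.12. Adhesion and egress genes counted 20 lower and 4 higher of 24, with the integrin chains Itgam at -3.84 ± 1.23 (2 sgRNAs read) and Itga4 at -1.68 ± 1.15. The adenosine and prostaglandin list had 12 lower and 2 higher of 14, with Enpp1 at 1.82 ± 1.56, with 54.3% of its CPM summed over the mice in Pan02 mouse 7, and Adora1 at -1.32 ± 1.21.

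Transporters needed for growth were lower in all 13 members, with the amino acid transporter Slc7a5 at -2.27 ± 1.16 and Slc33a1 at -1.10 ± 1.17. All 6 death receptors were lower, among them Tnfrsf25 at -0.85 ± 1.10 and Fas at -0.65 ± 1.14. Antigen presentation genes had 5 of 8 members lower and 3 higher, with the class II chain H2-Ab1 at 0.85 ± 1.35, with 71.9% of its CPM summed over the mice in Pan02 mouse 6, and the invariant chain Cd74 at -0.79 ± 1.11. B and T cell lineage genes, markers of the other lymphocytes, had 13 of 14 lower and 1 higher, with the T cell receptor chain Cd3g at -1.74 ± 1.18 and Cd40lg at 1.24 ± 1.51, with 96.1% of its summed CPM in Pan02 mouse 7. Taste receptors, a group without a known role in NK cells, had 25 of 28 lower and 3 higher, with Tas2r103 at -2.34 ± 1.17 and Tas2r104 at -1.80 ± 1.17. None of these values passed, and adjusted over the list alone, 1 gene passed, Itgam, with 0 in each of the other lists. Calhm2, alone in its list, came from the series title and so was chosen on these samples: its list is not independent evidence. Camera gave adjusted p between 0.881 and 0.941 for the 13 lists, and with an estimated correlation the adjusted p was 0.959 for each. The 3 named members above 0 turned sign under voom, to -2.96 for H2-Ab1, -2.94 for Cd40lg and -0.88 for Enpp1.

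In B16F10 mice no gene passed against culture by edgeR, and 115 genes had an unadjusted p under 0.05, no more than chance would give. The lowest p among higher genes fell on Gm20489 (3.68 ± 1.58), the water channel Aqp4 (3.66 ± 1.75) and Olfr1036 (3.74 ± 1.80), and 1 mouse held 79.7%, 87.8% and 78.3% of each gene's CPM summed over the 37 mice. The lowest among lower genes fell on Gm44579 (-7.31 ± 1.94), the receptor Notch2 (-4.15 ± 1.40) and Gfra1 (-3.97 ± 1.38), each below the culture mean in 9 of 9 mice. These 6 did not pass (adjusted p 0.476 for Gm44579 and 0.737 for the others, edgeR), and Calhm2 stood at -1.57 ± 1.13 (adjusted p = 0.737, edgeR, below the culture mean in 7 of 9 mice). At least 1 alternative setting put Calhm2 past the threshold in B16F10 mice, where voom called 2179 of 2859 genes. DESeq2 called 925 genes higher and 0 lower, and voom 0 higher and 2179 lower, with Aqp4 at -3.24, Gm20489 at -2.43 and Olfr1036 at -0.74. Aqp4 stood at -1.19 with capped sgRNAs. Without B16F10 mouse 1 edgeR called 34 genes, all lower.

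In E0771 mice 57 genes were lower than in culture and none was called higher (edgeR, with 141 genes at an unadjusted p under 0.05). Evi2 had 3 counts in all 10 mice together, a level 120-fold below culture (95% counting interval 41.1 to 582), Cd300ld3 had 3 counts (381-fold, 130 to 1846) and Gm49368 had 3 counts (518-fold, 177 to 2510). All 3 were below the culture mean in 10 of 10 mice, with adjusted p = 2.34e-20, 1.66e-18 and 5.28e-17 by edgeR, and were read through 1, 1 and 2 sgRNAs. Over the mice of all models their retention ratios were 0.872, 0.731 and 0.762, none past the threshold. Of the 57 genes, 11 had at most 4 sgRNAs that were read. In the 27 mice of the other models the 57 genes were retained at 0.892 of the expected number, and at 1.00 with counts under 2% of the highest elsewhere set to 0. Counted as sgRNAs detected, Evi2 (1.13), Gm49368 (0.55) and Cd300ld3 (1.03) had the opposite sign. With 3 counts each in these mice, that sign reflects the added 1 and the scaling, not more sgRNAs. Calhm2 stood at 0.31 ± 1.28 (adjusted p = 1.00, edgeR), with 7 of 10 mice below the culture mean, and at -4.97 under voom. At least 1 alternative setting put Calhm2 past the threshold in E0771 mice, where voom called 2525 of 2859 genes. TMMwsp scaling called 9 genes, TMM 7, both libraries of a mouse weighted equally 12, counts under 10 set to 0 32 and sgRNA-level scores 0, while 102 and 96 were called without E0771 mouse 1 and mouse 3. DESeq2 called 1730 higher and 143 lower, voom 0 higher and 2525 lower, and counting detected sgRNAs 289 higher and 23 lower.

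In Pan02 mice 3 genes were lower, each below the culture mean in 7 of 7 mice. Fcrl5, an Fc receptor-like protein of B cells, had a log2 fold change of -9.16 ± 2.05, Chrna9, a nicotinic receptor subunit, of -8.28 ± 1.90 and Slc29a2, a nucleoside transporter, of -7.25 ± 1.72, each through 20 sgRNAs (adjusted p = 0.0187, 0.0187 and 0.0237, edgeR). Calhm2 stood at -1.29 ± 1.15 (adjusted p = 0.718, edgeR; 6 of 7 mice below the culture mean), and at 0.25 with TMM scaling and 0.56 by DESeq2. No gene was called with TMMwsp or TMM scaling, with capped sgRNAs, by sgRNA-level scores or without any 1 of the 7 cultures, and 34, 11 and 5 were without Pan02 mouse 1, 3 or 5; simulated data with nothing changed gave 2 calls. DESeq2 called 418 higher and 0 lower, and voom 1 higher and 1186 lower.

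In GL261 mice 5 genes were lower and none was called higher. Grpr, the gastrin-releasing peptide receptor, fell by 9.46 ± 2.04 on the log2 scale (adjusted p = 0.00972, edgeR; 20 sgRNAs, below the culture mean in 11 of 11 mice). Evi2 had no count in any of the 11 mice, at least 120-fold lower than in culture against a floor of 3 counts over the group (adjusted p = 0.0141, edgeR). Itgam, the integrin chain CD11b of maturing NK cells, had 2 counts, 1241-fold below culture (343 to 10245, adjusted p = 0.0308, edgeR), through 2 sgRNAs. Over the mice of all models the retention ratio of Itgam was 0.996. Of the 5 genes, 4 had at most 4 sgRNAs that were read. Counted as sgRNAs detected, Evi2 (1.39) and Itgam (0.98) had the opposite sign. Evi2 had no count and Itgam 2 counts in these mice, so that sign reflects the added 1 and the scaling, not more sgRNAs. Calhm2 stood at -1.51 ± 1.23 (adjusted p = 0.909, edgeR, 10 of 11 mice below the culture mean). At least 1 alternative setting put it past the threshold in GL261 mice, where voom called 2379 of 2859 genes. Instead of 5 genes, 1 was called without GL261 mouse 1, 3, 7 or 10, 2 without mouse 11 and 3 without mouse 6. TMMwsp scaling called 2, counts under 10 set to 0 or counts under 2% of the highest elsewhere set to 0 called 1, and equal weight for both libraries of a mouse or sgRNA-level scores 0. DESeq2 called 1497 higher and 0 lower, and voom 0 higher and 2379 lower.

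Between the 4 models, 37 genes differed in summed reads (edgeR, 2850 genes tested, 329 with an unadjusted p under 0.05). The 3 with the lowest p were Adcy6, an adenylyl cyclase, Serinc3, a lipid scramblase that restricts retroviruses, and Cd40lg, the ligand of CD40 (adjusted p = 0.00532 each). Against B16F10 mice, Adcy6 stood at 3.65 in Pan02, -5.47 in E0771 and -2.76 in GL261 mice on the log2 scale. Serinc3 stood at 3.70, -6.39 and -0.50 in the same order, and Cd40lg at 7.96, 1.47 and 1.45. For each gene 1 Pan02 mouse held most of the gene's CPM summed over the 37 mice: 87.3% of Adcy6 lay in Pan02 mouse 1, 81.1% of Serinc3 in Pan02 mouse 6 and 96.1% of Cd40lg in Pan02 mouse 7, where Cd40lg took 18.9% of all reads, nearly all from a single sgRNA. Calhm2 did not pass between models (p = 0.453, adjusted p = 0.999, edgeR). At least 1 alternative setting put it past the threshold, among settings that called as many as 1687 of 2859 genes. With each sgRNA capped at the 99th percentile of its library, or with counts under 10 or under 2% of the highest elsewhere set to 0, 0 genes were called, 23 without the shallow mice, voom called 3, DESeq2 1687 and TMMwsp scaling 1239.

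Spleens of mice that received saline in place of library cells gave the background of the readout. The 2 Pan02 and 2 GL261 spleens of this kind held 11359 to 39923 counts, and 64 to 1466 of their sgRNAs reached 10 reads. In each of these 4 libraries, 100% of the sgRNAs with 10 reads or more had over 50 times as many reads in the library of another animal, where random sgRNAs matched on culture abundance had a mean of 11.0% to 69.9% and reached 78.03% in the highest of 100 draws. Mouse libraries under 100000 counts were those of E0771 mice 4, 5 and 7 and of GL261 mouse 8, 1 library in each. Of their sgRNAs with 10 reads or more, 100%, 98.2% and 97.3% in the libraries of E0771 mice 4, 5 and 7 had over 50 times as many reads in the library of another animal, and 68.97% in the GL261 mouse 8 library, where matched random sgRNAs gave a mean of 15.2%. The E0771 mouse 4 library held 3089 such sgRNAs, where 4637 were counted in the mouse as a whole.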

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

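All tests of explanations in this part were chosen after the results they bear on had been seen, and so were the comparisons of mice with cultures themselves. Samples far from their group were found in 15 of 46 groups tested, where chance marks about 1 in 20. That rate assumes normal values, while for some flagged gene levels the nearest mouse was at 0. The 11 GL261 mice exceed the group size that the outlier test covers and were not screened.

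Among the genes called lower in mice than in culture over all mice, all 5 called genes had at most 4 sgRNAs that were read, a property of 12 genes in all, so a small number of readable sgRNAs is a candidate explanation for these; in E0771 mice 11 of these 12 genes were called (91.7%) against 46 of the other 2847 (1.62%, Fisher's exact test, p = 8.51e-19), so it is a candidate for those 11 as well, as for the 4 of 5 called in GL261 mice (p = 8.89e-10), while 0 of the 3 called in Pan02 mice had so few, which argues against it there. In E0771 they made up 19.3% of the 57 genes called, which argues against it as the whole explanation there, although 24.6% of the 57 lay below a culture level under which only 0.821% of the other genes lay. Loss of cells carrying these sgRNAs predicts that the E0771 genes are also retained less often in the 27 mice of other models. They were, at 0.892 of the expected number (1779 for 1994, chance 1909 to 2084, permutation p = 0.0005), but at 1.00 (1432 for 1427, permutation p = 0.877) with counts under 2% of the highest elsewhere set to 0, a setting tried after the first value was seen, so loss cannot be told apart from reads passed between libraries, and a loss specific to E0771 mice stays untested.

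Each count was set against 100 divisions of the same samples, the real one among them. For E0771 only the real division, 1 of 100, gave as many calls (57 genes, highest other 0). The other divisions mix mice with cultures, so this shows only that mice and cultures differ as a whole. It cannot show whether the 57 genes fell beyond random loss of sgRNAs in single mice. Simulated E0771 data gave 30 false calls of 126 where changed genes shifted the scaling, and 0 calls with nothing changed. The sgRNA-level scores called 0 genes in E0771. Only the real division gave as many calls for Pan02 too (3 genes, highest other 0), with the same limit. Simulated data with nothing changed gave 2 calls there, so 3 calls stay weak evidence. For GL261 2 divisions did (5 genes, highest other 26), and as the other one called more genes than the real one, 5 calls stay weak evidence too. Over all mice 95 divisions did (5 genes, highest other 110), so chance cannot be excluded. For B16F10 all 100 did, as they must with a real count of 0 (highest other 0), which says nothing on chance. Divisions with 26 and 110 genes point to some structure of the samples, and which was not tested.

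Non-targeting sgRNAs were retained less often than targeting ones. GC content of the spacers was argued against as the whole explanation, since the ratio stayed at 0.972 when matched on it, though with coarser bins of abundance. So were reads passed between libraries, since the ratio stayed at 0.963 with such counts set to 0 (0.948 to 0.979). The ratio lay between 0.954 (without B16F10 mouse 1) and 0.981 (1 read or more) in the 6 alternatives run. No biological explanation was tested, and other differences in sequence between the spacers stay open.

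Reads were found in the 4 spleens of mice given saline and in 4 spleens without a tumor library. The spleens without a tumor library held 58545 counts (B16F10 mouse 10), 66811 (B16F10 mouse 11), 51170 (E0771 mouse 11) and 102375 (E0771 mouse 12), more than the 11359 to 39923 of the saline spleens. In all 8 libraries of both kinds, 99.96% or more of the sgRNAs with 10 reads or more held over 50 times as many reads in another animal's library, against a mean of 11.0% to 69.9% of random sgRNAs matched on culture abundance (78.03% in the highest draw), which is consistent with reads passing between libraries during preparation or sequencing. The cultured pool is argued against as their source, since 0 of the 8 correlated better with the mean culture than with another animal. Whether the 4 B16F10 and E0771 mice received library cells is not settled by the labels.

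B16F10 mouse 1 stood apart with 45325 sgRNAs at 10 reads or more (next 5820), a Gini index of 0.735 (next lowest 0.974), and levels, as log2(CPM + 1), of 1.20 for Gm44579, 3.04 for Evi2, 3.56 for Gm49368, 4.41 for Gm13769 and 3.16 for Cd300ld3. Pan02 mouse 1 kept 11786 sgRNAs at 10 reads or more (next 4362). Non-targeting sgRNAs took 11.1% of the reads in E0771 mouse 4 (next 8.46) and 27.1% in Pan02 mouse 3 (next 10.1). Further single mice stood apart at levels on that scale of 0.29 for Evi2 in E0771 mouse 7, 7.34 for Gm49368 in Pan02 mouse 3, 0.50 for Gm13769 in E0771 mouse 1 and 0.38 for Cd300ld3 in Pan02 mouse 5. In culture 5 the top sgRNA took 0.0551% of reads (next 0.0206), and this sgRNA, Ryk_11, was also the top one of GL261 mouse 7, at 4.73%. The top sgRNAs of 2 further cultures were likewise the top ones of a mouse, Lpar6_12 of culture 4 in B16F10 mouse 5 (2.38%) and Kcnmb1_8 of culture 7 in GL261 mouse 2 (5.56%).

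Models differed in the share of the top sgRNA (first named minus second) by 1.31 points between B16F10 and E0771, -6.39 between B16F10 and Pan02, -7.71 between E0771 and Pan02 and -5.88 between E0771 and GL261, and in sgRNAs with 10 reads or more by 5634 between B16F10 and GL261, which rested on B16F10 mouse 1 (1086 without it, adjusted p = 0.239, exact permutation test). In summed reads 37 genes differed between models, among them Adcy6, Serinc3 and Cd40lg at adjusted p = 0.00532 (edgeR). Of 100 divisions of the mice, the real one included, 12 gave as many genes (highest other 56), so chance cannot be excluded for this count.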

How the results depend on the processing

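No alternative here was planned for these comparisons, since all comparisons of mice were set after the table had been seen; the kinds of setting had been fixed for the tissue comparisons. No paired analysis was possible because the columns of a mouse do not say which is tumor and which is spleen, so a block by mouse could not be fitted; the planned mouse block, the addition of spleens without a tumor library and all settings of the tissue comparisons were not run. Among named values 522 alternatives kept direction and side of the threshold, 37 gained and 66 lost it in the same direction and 87 turned sign; among the main counts and values 238 stayed and 90 moved. The cause was not tested except where stated. Depth was lowest in the 4 mouse libraries under 100000 reads; thinned to 3785469 reads, mice of each model still held fewer sgRNAs than cultures. Retention over all mice called 0 genes under each of its 6 alternatives (exact test). In these, 116 to 142 genes had an unadjusted p under 0.05, no more than chance would give.

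DESeq2 called 925 genes in B16F10, 1873 in E0771, 418 in Pan02, 1497 in GL261, 1837 over all mice and 1687 between models; voom called 2179, 2525, 1187, 2379, 2858 and 3, and the number of sgRNAs detected 367, 312, 511, 433, 96 and 242. sgRNA-level scores called 0 genes in E0771, Pan02, GL261 and over all mice. TMMwsp scaling called 9 in E0771, 0 in Pan02, 2 in GL261, 1 over all mice and 1239 between models; TMM 7 in E0771, 0 in Pan02, 2 over all mice and 124 between models; non-targeting size factors 6 in Pan02, 3 over all mice and 67 between models. Capped sgRNAs gave 0 in Pan02, 2 over all mice and 0 between models. Counts under 10 set to 0 gave 1 in B16F10, 32 in E0771, 1 in GL261 and 0 between models. Equal weight for both libraries gave 12 in E0771, 0 in GL261 and 3 over all mice. Counts under 2% of the highest elsewhere set to 0 gave 1 in GL261 and 0 between models, and a median of 1273 sgRNAs with 10 reads or more in E0771 mice instead of 3480. Without shallow mice 3 genes were called over all mice and 23 between models. Of 201 members of the gene lists 177 were lower over all mice, against 5 with TMMwsp, 77 with TMM, 10 by DESeq2, 47 by number of sgRNAs detected and 97 by sgRNA-level scores. In B16F10 retention, 0 genes instead of 1 passed at 1 read, at 100 reads and with the 2% filter. Dominant events numbered 716 at 1% and 89 at 5% by construction; at 5% the adjustment over only genes with an event let 76 of 76 pass, though the highest count was one that permutations reach (p = 0.912).

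Leaving out 1 mouse or culture gave 0 to 34 genes in B16F10 (34 without mouse 1), 51 to 102 in E0771 (102 without mouse 1, 96 without mouse 3), 0 to 34 in Pan02 (34, 11 and 5 without mice 1, 3 and 5; 0 without any culture), 1 to 7 in GL261 (1 without mouse 1, 3, 7 or 10, 2 without mouse 11, 3 without mouse 6), 3 to 7 over all mice (3 without Pan02 mouse 3, 4 or 6 or any culture) and 25 to 42 between models.

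Values whose sign turned from the main one were these, over all mice unless a model is named. Over all mice the median of all genes moved too, by 2.37 with TMMwsp, 3.50 by DESeq2, 0.84 by sgRNAs detected, 0.83 with TMM and -2.74 by voom. A turned sign therefore need not be a change of that gene against the others. TMMwsp scaling gave Ackr3 0.34, Acvrl1 0.42, Adora1 1.45, Calhm2 0.50, Cd244a 1.37, Cd74 2.10, Cxcr3 1.07, Fas 0.98, Ifngr2 0.74, Il4ra 0.36, Itga4 0.57, Sigirr 0.13, Slc33a1 0.34, Slc7a5 0.39, Tas2r103 0.70, Tas2r104 0.11, Tnfrsf25 1.83. DESeq2 gave Ackr3 1.34, Acvrl1 1.36, Calhm2 0.55, Cd244a 2.85, Cd3g 1.60, Cd74 3.85, Cxcr3 1.80, Eng 1.55, Fas 1.61, Ifngr2 2.41, Itga4 2.74, Sigirr 1.98, Slc33a1 0.71, Tas2r103 2.12, Tas2r104 1.36, Tnfrsf25 3.29, and in Pan02 Calhm2 0.56. The number of sgRNAs detected gave Ackr3 0.13, Acvrl1 0.14, Calhm2 0.10, Cd300ld3 1.38, Cd40lg -0.032, Cxcr3 0.17, Eng 0.22, Evi2 1.20, Fas 0.054, Gm13769 0.46, Gm49368 0.78, Ifngr2 0.098, Itgam 0.93, Klrb1b 0.23, Slc33a1 0.031, Tnfrsf25 0.34, in B16F10 Aqp4 -0.11, Calhm2 0.011, in E0771 Cd300ld3 1.03, Evi2 1.13, Gm49368 0.55, in Pan02 Calhm2 0.20, and in GL261 Calhm2 0.14, Evi2 1.39, Itgam 0.98. sgRNA-level scores (mean z, not log2) gave Adora1 0.48, Calhm2 0.47, Cd300ld3 0.80, Cd40lg -0.063, Cxcr3 0.089, Eng 0.29, H2-Ab1 -0.076, Sigirr 0.18, Slc33a1 0.18, Slc7a5 0.10, Tnfrsf25 0.070, in B16F10 Aqp4 -0.51, Calhm2 0.14, in Pan02 Calhm2 0.25, and in GL261 Calhm2 0.50. Voom gave Cd40lg -2.94, Enpp1 -0.88, H2-Ab1 -2.96, in B16F10 Aqp4 -3.24, Gm20489 -2.43, Olfr1036 -0.74, and in E0771 Calhm2 -4.97. TMM scaling gave Cd74 0.17, Fas 0.15, Tnfrsf25 0.59, and in Pan02 Calhm2 0.25. Capped sgRNAs gave Cd40lg -0.81, and in B16F10 Aqp4 -1.19.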

Other observations

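All tests in this part were chosen after the data had been seen. The genes named here from the E0771 comparison lie outside the fixed rule and were chosen after their values were seen.

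Beyond the 3 genes named in the report, the genes lower in E0771 mice than in culture (edgeR, 57 in all) were read through a median of 20 sgRNAs. Ifngr2, a chain of the interferon-gamma receptor, stood at -6.15 ± 1.60 (adjusted p = 0.00772, edgeR), Tlr1, a receptor for bacterial lipopeptides, at -7.79 ± 1.66, the scavenger receptor Scarb1 at -5.77 ± 1.55 and the sialic acid O-acetyltransferase Casd1 at -8.17 ± 1.74. Olfactory receptors made up 13 of the 57 genes where 11.0 were expected from their share of the genes tested (two-sided Fisher's exact test, p = 0.499). Members of the 13 fixed lists were 2, Ifngr2 and the taste receptor Tas2r103 (-7.53 ± 1.64, adjusted p = 0.000689, edgeR).

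Olfactory receptors as a family of 554 genes were retained slightly more often than expected over all mice (ratio 1.02, adjusted p = 0.0210, permutation over sgRNAs), and at 1.00 (adjusted p = 0.982) when matched on the GC content of their spacers as well. The excess thus did not hold in that setting. As the setting also matched abundance in coarser bins, the change cannot be credited to GC content alone.

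The 2 libraries of a mouse resembled each other more than random pairs of libraries of the same model, with a mean correlation across sgRNAs of 0.358 against 0.142 (p = 0.0001, the smallest that 10000 random pairings can give; sgRNAs are not independent replicates). Saline spleens, which got no library cells, correlated at 0.637 to 0.878 with their closest library, so a correlation need not mean shared cells. Whether reads passed between libraries raised the values within mice was not tested. The leading sgRNAs of the 2 libraries differed: among the 50 most abundant sgRNAs of each library, only 4 of 37 mice shared any, and Pan02 mouse 6 shared the most, 13. Mice of the same model correlated at a median of 0.106, mice of different models at 0.0559, and cultures with each other at 0.927.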
